A study of Mus musculus with 16 samples.

How the data were processed

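Lung homogenates of mouse pups at postnatal day 3 were profiled with a one-colour Agilent oligonucleotide microarray, 1 array per sample, for 4 groups of 4 arrays: wild type and Fgf10+/-, each in normoxia or in 85% oxygen from day 0 to day 3. Per the labels, total RNA was extracted with a miRNeasy kit, amplified and labelled with Cy3 in a single-colour kit. The deposited values are log2 intensities of the array features, and they were used as the authors deposited them. Their maximum lies near 16, the log2 of the highest value of a 16-bit scanner, and the array medians differ by at most 0.00068, so the values were read as quantile normalized between arrays, which the labels do not state. Background correction, scan settings, litter, and slide or scan batch are not given in the sources used here. The design is taken as unpaired, since the replicate numbers showed no strong pairing across the groups (same-number correlations of the residuals between -0.03 and 0.09). For replicates 1 to 4 the correlations were 0.087, 0.017, 0.022 and 0.074 between the genotypes in normoxia, and 0.004, -0.029, 0.022 and 0.057 in hyperoxia. A weak pairing is therefore not excluded. The signal range limits what can be read: Sftpc lies at the upper end of the scale in all arrays.

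Features were matched to genes through the platform annotation. Of the features, 31465 name 1 gene symbol, 0 name several and 31511 name none. The latter include control features, and the 31490 of them without a missing value were tested apart from the named genes. Names were brought up to date through RefSeq accessions for 29036 features, while 2075 symbols were current, 349 were unique synonyms and 5 kept the name of the annotation. The RefSeq table belongs to assembly GRCm38.p6 and served only for names and for the order of genes along chromosomes. A feature was kept if it lay above the 25th percentile of its array in at least 4 of 16 arrays, and each gene was represented by the kept feature with the highest mean, which left 20166 genes, 5970 of them with several kept features. There were 33 missing values, at most 1 per feature.

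Differential expression was tested with limma 3.58.1 in R 4.3.3: 1 linear model of all 16 arrays with a mean per group and empirical Bayes moderation (12 residual and 2.129 prior degrees of freedom), so that even comparisons of 4 against 4 arrays rest on a pooled spread. The contrasts were hyperoxia in each genotype, genotype in each oxygen level, and their interaction. P-values were adjusted by Benjamini and Hochberg within each contrast, with calls at an adjusted p under 0.05. For Fgf10, group differences were also tested by exact two-sided permutation of the array labels, whose smallest possible p with 4 against 4 arrays is 0.0286. Gene lists were tested with camera of limma at its preset inter-gene correlation of 0.01, adjusted over 41 lists per contrast. Every adjusted p of a list, and every adjusted p after leaving out an array, comes from these limma functions. The sex-linked genes served as a check of the samples and were not among the lists tested. Some lists share members: Cdkn1a counts both for the p53 targets and for transitional epithelium, and Pdpn both for type 1 cells and for lymphatic endothelium.

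The groups, contrasts, tests, gene lists, the filter, the choice of feature and the alternatives were fixed before the data were examined, except the heat-shock covariate, the test of features that name no gene, and the tests of explanations that the closing section names as chosen later. The rule for the genes named was fixed at the same time: per contrast, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap, without sex-linked genes and genes known only by a clone or model name. Where fewer than 5 genes passed, the rule takes the 5 with the smallest p. It adds up to 4 members with the smallest p of each list discussed, and always Fgf10, Sftpc, Abca3 and Ager. Genes whose features passed with opposite signs were to be named as uncertain, and no named gene had such features. Genes named outside this rule are said to be chosen after their values were seen.

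The alternatives changed 1 choice at a time: no filter, or a filter at the 50th percentile; the mean of all features of a gene; shifting arrays to a common 75th percentile or quantile normalizing them again; limma with trend and robust options; array weights; a fit to only the groups compared; a fold minimum of 1.5; replicate number as a block; a covariate for sex; and each array left out in turn. For lists they were an estimated correlation, ranks, and the rotation test fry. The scaling and quantile steps were run over the tested genes, because over all features the deposited values leave them nothing to move. Other splits of the same arrays were counted for each contrast.

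The pipeline was tested on simulated data, in which 200 of 20166 genes were changed. In the genotype comparison in normoxia it recovered 21.7% of genes changed 1.5-fold, 57.8% of those changed 2-fold and 85.1% of those changed 4-fold, with 3 false calls. For the interaction the shares were 5.33%, 34.4% and 65.6%, again with 3 false calls. The hyperoxia comparisons held more false calls, 10 in wild type and 9 in Fgf10+/-. For 1.5-fold, 2-fold and 4-fold changes, 22 of 62, 34 of 62 and 65 of 76 genes were recovered in wild type. In Fgf10+/- the numbers were 21 of 83, 31 of 64 and 44 of 53. Each comparison was simulated only 1 time, so these numbers do not fix the rate of false calls. A list of alveolar type 2 genes shifted by 0.5 (log2) was called in 20 of 20 simulations, with 1 call of another list. The simulated genes varied independently of each other. In the data the estimated correlation between genes was 0.168 for the type 2 list and 0.589 for the mitosis list. The simulations therefore do not show how often the list test makes false calls in these data. The number of arrays limits the precision, and changes of 1.5-fold were missed more often than found at this size. Raw scanner files were not used here.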

Results

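Gene expression was measured in lung homogenates of mouse pups at postnatal day 3 with a one-colour Agilent oligonucleotide microarray. The pups were wild type or were labelled Fgf10+/-, which means that they carry 1 inactivated copy of the gene for fibroblast growth factor 10, a mesenchymal growth factor that directs branching and epithelial growth in the developing lung. Within each genotype, pups stayed in normoxia or breathed 85% oxygen from postnatal day 0 to day 3, an exposure used in rodents to model bronchopulmonary dysplasia. The 4 groups held 4 arrays each, 16 in all, and the log2 intensities of 20166 named genes were tested. Replicate arrays of a group correlated across all tested genes with r between 0.974 and 0.983. The number of arrays limits the precision. The labels treat the replicates as separate samples and do not say whether they came from separate litters, so the p-values measure only the spread between these samples. By the Y-linked gene Eif2s3y and by Xist, 1 of 4 wild-type normoxia arrays, 2 of 4 wild-type hyperoxia arrays, 2 of 4 Fgf10+/- normoxia arrays and 1 of 4 Fgf10+/- hyperoxia arrays came from male tissue.

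Fgf10 itself was examined first, as the targeted gene. Its signal, averaged over 10 features, was 7.59 ± 0.20 (log2, SD, n = 4) in wild-type normoxia, 7.89 ± 0.21 in normoxia arrays labelled Fgf10+/-, 7.49 ± 0.18 in wild-type hyperoxia and 7.28 ± 0.22 in hyperoxia arrays labelled Fgf10+/-. In normoxia all 10 features were higher in the arrays labelled Fgf10+/-, and the mean difference was 0.30 (exact two-sided permutation p = 0.143, n = 4 per group). In hyperoxia 0 of 10 features were higher in the arrays labelled Fgf10+/-, with a mean difference of -0.21 (exact permutation p = 0.229, n = 4 per group). The features were read on the same arrays, so their number adds no replicates. The feature with the highest mean, which stands for the gene in all tests below, gave 0.48 (SE 0.20, 95% interval 0.04 to 0.92, limma adjusted p = 0.334) in normoxia and -0.21 (SE 0.20, 95% interval -0.65 to 0.22, limma adjusted p = 0.835) in hyperoxia. The signal was therefore not measurably lower in the arrays labelled Fgf10+/-, and the genotype names below are those of the labels. A feature outside the deleted part of the gene checks nothing about the label, and the position of the features relative to the deleted part is not given in the sources used here. Hyperoxia lowered the Fgf10 signal in pups labelled Fgf10+/- by the limma test (-0.64, SE 0.20, adjusted p = 0.0346). The exact permutation p was 0.0286, the smallest that 4 against 4 arrays allow, for the mean of the features and 0.0571 for the feature tested. That call was lost in a fit to these 8 arrays alone (adjusted p = 0.0586). It was also lost without replicate 2 (0.0679), 3 (0.0657) or 4 (0.109) of the normoxia arrays and without replicate 1 (0.0982), 3 (0.0544) or 4 (0.0819) of the hyperoxia arrays. In wild-type pups the change was 0.06 (SE 0.20, adjusted p = 0.897), and the test of the difference between the genotypes did not pass (interaction -0.69, SE 0.29, adjusted p = 0.737).

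**Figure D1:**
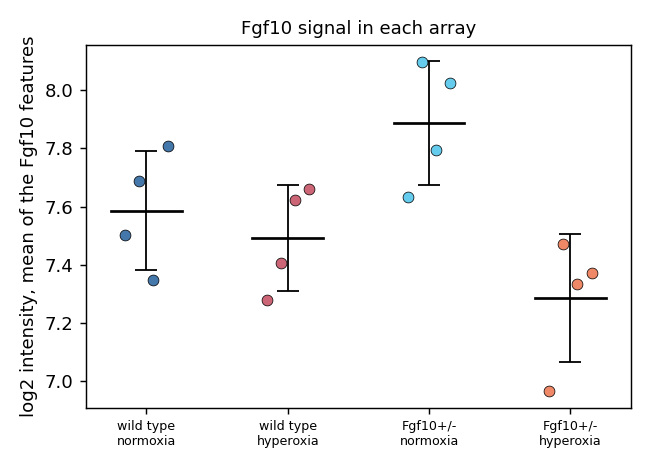
Mean log2 intensity of the 10 Fgf10 features in each array (points), by genotype and oxygen level, with the group mean and SD. The normoxia arrays labelled Fgf10+/- lie between 7.63 and 8.10 and the wild-type normoxia arrays between 7.35 and 7.81, so the targeted gene does not separate the genotypes.

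The first comparison asked how the wild-type lung responds to 85% oxygen. The antioxidant enzyme gene Gpx2 rose 8.44-fold (log2 3.08, SE 0.16), and the cell cycle inhibitor Cdkn1a rose by 1.90 (SE 0.13). Genes of cell division fell, among them the centromeric histone variant Cenpa (7.03-fold lower, log2 -2.81, SE 0.22) and cyclin Ccnb2 (5.47-fold lower, log2 -2.45, SE 0.18). At a limma adjusted p under 0.05, 2082 genes rose and 1764 fell, 3846 of 20166, with n = 4 arrays per group. Of these, 711 changed at least 2-fold.

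The largest measured rise in wild-type pups was in Nmrk2, a nicotinamide riboside kinase of NAD synthesis, from 3.97 ± 1.24 to 9.45 ± 0.39 (log2, SD, n = 4), a difference of 5.48 (SE 0.53, adjusted p = 1.87e-05). Its normoxia mean lies under the array median of 4.50, near the 25th percentile of features (3.69), so neither its fold nor its place among the rises can be read exactly. The normoxia means of Kng1 (4.43) and Bpifa1 (4.41) also lie under that median. The chemokine genes Cxcl17 (7.85-fold, log2 2.97, SE 0.29) and Cxcl5 (6.79-fold, log2 2.76, SE 0.62) rose, as did Reg3g, an antimicrobial lectin (5.94-fold, log2 2.57, SE 0.34), and the airway secretory gene Bpifa1 (log2 2.49, SE 0.24). Other large rises were those of kininogen Kng1 (log2 2.78), the methyltransferase Inmt (2.76), Calca, which encodes calcitonin gene-related peptide (2.74), and the water and glycerol channel Aqp3 (2.51). The largest falls included Cenpa, the mitotic regulator Cdca3 (log2 -2.72, SE 0.21) and Iqgap3, a scaffold protein of proliferating cells (-2.99, SE 0.47). Iqgap3 stood at 3.01 in replicate 3 of the hyperoxia arrays, under the array median, against 5.28 in the other 3, and without that array its change was -2.42, smaller than those of Cenpa (-2.67) and Cdca3 (-2.53). They were followed by the histone genes H2ac4 (-2.55) and H1f5 (-2.51), the kinetochore gene Spc24 (-2.42), the mitotic kinesin Kif20a (-2.42), topoisomerase Top2a (-2.41) and Shcbp1 (-2.41). By the naming rule, all 4 arrays of one group lay beyond all 4 of the other for each of these genes. Without any effect 2.86% of genes would separate so, and 24.8% did. Adjusted p-values of these 20 genes lay between 3.11e-07, for Gpx2, and 0.00608, for Cxcl5.

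Gene lists fixed beforehand described the same arrays by pathway. Of 18 measured genes of mitosis, 16 fell and 2 did not pass (17 fell adjusted over the list alone, median -1.91), with Bub1b at -2.40 (SE 0.17) and Birc5 at -2.41 (SE 0.22). Of 15 genes of DNA replication, 14 fell (14 adjusted over the list alone, median -1.25), among them the ribonucleotide reductase subunit Rrm2 (-2.08, SE 0.24), Rfc3 (-1.43, SE 0.16) and Mcm2 (-1.25, SE 0.15). By the camera list test the adjusted p-values were 2.68e-20 and 5.01e-14, and for both lists adjusted p = 0.15 with an estimated correlation between genes. Of 20 targets of p53, 12 rose and 8 did not pass (12 rose adjusted over the list alone, median 0.61, camera adjusted p = 1.2e-07). Besides Cdkn1a these included Ccng1 (1.14, SE 0.12), the nuclease gene Aen (0.93, SE 0.10) and the apoptosis gene Bbc3 (1.03, SE 0.12). This was the only list whose call held with an estimated correlation (adjusted p = 0.00181). Of 21 targets of the oxidative stress factor NRF2, 13 rose and 8 did not pass (15 rose and 1 fell adjusted over the list alone, median 0.80, adjusted p = 2.32e-09, and adjusted p = 0.164 with an estimated correlation). They included the glutathione transferase Gsta3 (1.83, SE 0.14), Aox1 (1.64, SE 0.15) and Gclc, the catalytic subunit of glutathione synthesis (1.41, SE 0.13).

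Markers of airway cells rose in wild-type hyperoxia. Of 16 ciliated cell genes, 10 rose and 6 did not pass (13 adjusted over the list alone, median 0.80, camera adjusted p = 6.03e-07, and adjusted p = 0.269 with an estimated correlation). The tektins Tekt1 (1.27, SE 0.21) and Tekt4 (1.31, SE 0.23) and the axonemal gene Cfap52 (1.66, SE 0.27) were among them. Of 10 club cell genes, 6 rose and 4 did not pass (8 adjusted over the list alone, median 0.81, adjusted p = 4.54e-05, and adjusted p = 0.225 with an estimated correlation). Aldh1a1 rose by 1.87 (SE 0.13), the secretoglobins Scgb3a1 by 1.98 (SE 0.32) and Scgb3a2 by 0.93 (SE 0.16), along with Reg3g. Of 13 genes of damage-associated transitional epithelium, 7 rose and 6 did not pass (8 adjusted over the list alone, median 0.37, adjusted p = 0.000479, and adjusted p = 0.225 with an estimated correlation). These were Cdkn1a, which is also a p53 target, the keratins Krt8 (1.02, SE 0.09) and Krt19 (1.09, SE 0.12), and galectin Lgals3 (1.12, SE 0.26) among others. Of 14 alveolar type 1 cell genes, 6 rose and 8 did not pass (6 adjusted over the list alone, median 0.22, adjusted p = 0.0251, and adjusted p = 0.362 with an estimated correlation). Hopx (1.04, SE 0.10), Gprc5a (0.71, SE 0.11) and Pdpn (0.61, SE 0.11) led that list. The type 1 list lost its call without replicate 3 of the hyperoxia arrays (0.14, adjusted p = 0.0601). The type 1 marker Ager stood at -0.18 (SE 0.11, adjusted p = 0.311), and the type 2 cell gene Abca3, a lipid transporter of lamellar bodies, rose by 0.30 (SE 0.10, adjusted p = 0.0443), a call lost in 8 of 8 fits that left out 1 array. The surfactant gene Sftpc lay at the upper end of the scale in every array (15.98 to 15.99 in the group means), where no difference can be read.

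Other lists moved in wild-type hyperoxia as well. Of 7 genes of MHC class II antigen presentation, 5 fell and 2 did not pass (6 adjusted over the list alone, median -1.16, camera adjusted p = 0.000158, and adjusted p = 0.225 with an estimated correlation). H2-DMa stood at -1.43 (SE 0.18), H2-Aa at -1.41 (SE 0.27) and the invariant chain Cd74 at -1.20 (SE 0.28). Of 18 genes of elastic fibres and collagens, 8 fell, 1 rose and 9 did not pass (9 fell and 1 rose adjusted over the list alone, median -0.35, adjusted p = 0.000479, and adjusted p = 0.385 with an estimated correlation). The fibrillins Fbn1 (-0.85, SE 0.14) and Fbn2 (-0.52, SE 0.10) fell and Eln, which encodes elastin, rose (1.25, SE 0.27). Of 14 genes of FGF signalling targets and feedback, 4 fell and 10 did not pass (4 adjusted over the list alone, median -0.17, adjusted p = 0.0198, and adjusted p = 0.15 with an estimated correlation). The 4 were Etv4 (-1.32, SE 0.28), a transcription factor induced by FGF receptors, Sox9 (-0.97, SE 0.21), the feedback inhibitor Spry1 (-0.87, SE 0.15) and Bmp4 (-0.67, SE 0.21, lost in 6 of 8 fits that left out 1 array). Of 18 genes of cholesterol and fatty acid synthesis, 6 rose, 1 fell and 11 did not pass (9 rose and 1 fell adjusted over the list alone, median 0.30, adjusted p = 0.00984, and adjusted p = 0.225 with an estimated correlation). The desaturase Scd1 rose by 0.90 (SE 0.15) and Acaca by 0.63 (SE 0.11). Of 6 mast cell genes, 3 fell and 3 did not pass (4 adjusted over the list alone, median -0.57, adjusted p = 0.0295, and adjusted p = 0.225 with an estimated correlation), and the call was lost without replicate 2 of the hyperoxia arrays (adjusted p = 0.0727). Of the genes that fell, Tpsb2 lost its call in 8 and Mcpt8 in 5 of 8 fits that left out 1 array, and Cpa3 in 0. One wild-type normoxia array, replicate 4, carried skeletal muscle genes at a mean of 8.36 against 4.60 in the other 3, and brown fat genes at 7.23. Without it 3192 genes passed in wild-type hyperoxia, 1687 higher and 1505 lower.

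The next comparison asked the same question in pups labelled Fgf10+/-. Gpx2 rose 7.89-fold (log2 2.98, SE 0.16), and Cdkn1a rose by 2.46 (SE 0.13). Nmrk2 rose by 4.87 (SE 0.53) from a normoxia mean of 3.92, which is under the array median of 4.50, so its fold cannot be read exactly. All 18 measured mitosis genes fell, with Bub1b at -2.06 (SE 0.17). In total 2630 genes rose and 2161 fell, 4791 of 20166 (limma, n = 4 arrays per group), and 1002 of them changed at least 2-fold.

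Among the largest rises in pups labelled Fgf10+/- were Inmt (13.1-fold, log2 3.71, SE 0.31), Calca (12.9-fold, log2 3.69, SE 0.31), Cxcl17 (9.31-fold, log2 3.22, SE 0.29) and Kng1 (7.72-fold, log2 2.95, SE 0.39). The protease inhibitor Serpina3n (log2 2.86, SE 0.59), the aldehyde dehydrogenase Aldh3a1 (2.74, SE 0.22), Gdpd2 (2.71, SE 0.28) and Ms4a4d (2.55, SE 0.32) completed the 10 largest. For Serpina3n and Ms4a4d the lower group mean (2.99 and 3.88) lies under the array median of 4.50, so the size of these rises is uncertain. The largest falls were in the linker histone H1f5 (7.06-fold lower, log2 -2.82, SE 0.21), the transmembrane protein Slitrk6 (6.45-fold lower, log2 -2.69, SE 0.44) and the cyclin-dependent kinase subunit Cks2 (5.3-fold lower, log2 -2.41, SE 0.20). They were followed by the kinetochore genes Ska1 (-2.37), Spc24 (-2.15) and Nuf2 (-2.13), the RNA-binding protein Mex3a (-2.33), the acyl-CoA thioesterase Acot3 (-2.19, to a mean of 4.17, also under that median), the homeobox gene Hoxa7 (-2.17) and the imprinted gene Dlk1 (-2.10). By the naming rule, each of these genes separated the 4 hyperoxia arrays from the 4 normoxia arrays. Of all tested genes 24.9% did so, and 2.86% would without any effect. The adjusted p-values of the named genes lay between 2.62e-07, for Gpx2, and 0.00269, for Serpina3n.

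By list, 18 of 18 mitosis genes fell (18 adjusted over the list alone, median -1.47, camera adjusted p = 7.68e-15) and 14 of 15 DNA replication genes fell (14 adjusted over the list alone, median -1.11, adjusted p = 2.42e-11) in pups labelled Fgf10+/-. For both lists adjusted p = 0.153 with an estimated correlation. Of 20 p53 targets, 14 rose, 1 fell and 5 did not pass (14 rose and 1 fell adjusted over the list alone, median 0.78, adjusted p = 4.94e-09), with Cdkn1a, the ubiquitin ligase gene Mdm2 (0.84, SE 0.08), Aen (0.98, SE 0.10) and Phlda3 (1.21, SE 0.14). This was again the only list to hold with an estimated correlation (adjusted p = 0.000734). Of 21 NRF2 targets, 13 rose and 8 did not pass (14 rose and 1 fell adjusted over the list alone, median 0.90, adjusted p = 3.53e-08, and adjusted p = 0.153 with an estimated correlation), with Gsta3 at 2.21 (SE 0.14) and Aox1 at 1.88 (SE 0.15). Of 21 hypoxia-inducible genes, 8 rose, 1 fell and 12 did not pass (8 rose and 1 fell adjusted over the list alone, median 0.33, adjusted p = 0.00261, and adjusted p = 0.108 with an estimated correlation). Those that rose included the glycolytic genes Aldoa (0.84, SE 0.10) and Eno1 (0.74, SE 0.10) and the glucose transporter Slc2a1 (1.37, SE 0.19). In wild-type hyperoxia 5 of these 21 genes rose, 1 fell and 15 did not pass (median 0.18, camera adjusted p = 0.151, fry adjusted p = 0.00026). Of 14 FGF targets and feedback genes, 4 fell in pups labelled Fgf10+/-, as many as in wild type, and 10 did not pass (median -0.14). Camera did not call that list (adjusted p = 0.139), fry did (0.00455), and it was not among the lists called for the interaction.

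Epithelial lists rose in pups labelled Fgf10+/-. Of 20 alveolar type 2 genes, 10 rose, 2 fell and 8 did not pass (10 rose and 2 fell adjusted over the list alone, median 0.38, camera adjusted p = 0.00246, and adjusted p = 0.317 with an estimated correlation). S100g rose by 2.15 (SE 0.17), the protease Ctsh by 1.40 (SE 0.13) and the surfactant lipid enzyme Lpcat1 by 1.23 (SE 0.12), while Egfl6 stood at -0.91 (SE 0.13). Abca3 rose by 0.52 (SE 0.10, adjusted p = 0.00165). Of 14 type 1 genes, 9 rose, 1 fell and 4 did not pass (9 rose and 1 fell adjusted over the list alone, median 0.50, adjusted p = 4.31e-05, and adjusted p = 0.153 with an estimated correlation), among them Hopx (1.37, SE 0.10) and Ager (0.51, SE 0.11). Of 13 transitional epithelium genes, 8 rose and 5 did not pass (10 adjusted over the list alone, median 0.73, adjusted p = 1.66e-06, and adjusted p = 0.153 with an estimated correlation). Krt8 rose by 1.40 (SE 0.09) and Krt19 by 1.49 (SE 0.12). Of 10 club cell genes, 7 rose (8 adjusted over the list alone, median 0.92, adjusted p = 9.57e-06, and adjusted p = 0.177 with an estimated correlation). Of 16 ciliated cell genes, 12 rose (15 adjusted over the list alone, median 1.02, adjusted p = 2.93e-08, and adjusted p = 0.249 with an estimated correlation). In wild-type hyperoxia 7 of the 20 type 2 genes rose, 2 fell and 11 did not pass (median 0.11). There camera did not call the type 2 list (adjusted p = 0.163) and fry did (0.0221).

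In mesenchymal and immune lists of the pups labelled Fgf10+/-, all 7 MHC class II genes fell (7 adjusted over the list alone, median -1.31, camera adjusted p = 2.05e-05, and adjusted p = 0.153 with an estimated correlation), with the transactivator Ciita at -1.66 (SE 0.30, to a mean of 3.75, under the array median of 4.50). Of 18 genes of elastic fibres and collagens, 8 fell, 2 rose and 8 did not pass (8 fell and 2 rose adjusted over the list alone, median -0.38, adjusted p = 0.00261, and adjusted p = 0.476 with an estimated correlation). Fbn1 stood at -0.91 (SE 0.14) and Fbn2 at -0.67 (SE 0.10). Of 11 alveolar myofibroblast genes, 3 fell, 1 rose and 7 did not pass (6 fell and 1 rose adjusted over the list alone, median -0.46, adjusted p = 0.0377, and adjusted p = 0.476 with an estimated correlation). The growth factor receptor Pdgfra (-1.49, SE 0.19), Hhip (-0.73, SE 0.13) and Lgr6 (-0.82, SE 0.22) fell, and Eln rose (0.97, SE 0.27). The call of Lgr6 was lost in 1 and that of Eln in 2 of 8 fits that left out 1 array. The myofibroblast call was lost without replicate 4 of the normoxia arrays (adjusted p = 0.118) and without replicate 1 of the hyperoxia arrays (0.106). Of 6 lymphatic endothelial genes, 3 rose, Mmrn1 (1.49, SE 0.13), Lyve1 (0.86, SE 0.27, lost in 5 of 8 such fits) and Pdpn, which is also on the type 1 list (3 adjusted over the list alone, median 0.66, adjusted p = 0.0205, and adjusted p = 0.339 with an estimated correlation). That call was lost without replicate 3 of the normoxia arrays (adjusted p = 0.0851). Of 12 glucocorticoid-responsive genes, 5 rose and 7 did not pass (6 adjusted over the list alone, median 0.42, adjusted p = 0.0236, and adjusted p = 0.417 with an estimated correlation). The metallothioneins Mt1 (1.37, SE 0.21) and Mt2 (1.10, SE 0.22) were 2 of them. It lost its call without replicate 2 of the normoxia arrays (adjusted p = 0.0714) and without replicate 1 of the hyperoxia arrays (0.0723). Of 19 inflammatory cytokine and chemokine genes, 3 rose, Cxcl5 (2.53, SE 0.62), the cyclooxygenase gene Ptgs2 (1.30, SE 0.26) and Timp1 (0.92, SE 0.28, lost in 5 of 8 such fits), and 16 did not pass (3 adjusted over the list alone, median 0.59, adjusted p = 0.0377, and adjusted p = 0.618 with an estimated correlation). Replicate 1 of the hyperoxia arrays held this list at a mean of 7.06 against 5.62 in the other 3, and without it the median was 0.15 (adjusted p = 0.346). The inflammatory call was also lost without replicate 3 (0.077) or replicate 4 (0.0884) of the normoxia arrays. Without replicate 1 of the hyperoxia arrays 4037 genes passed, and without replicate 2, which carried liver genes at a mean of 5.49 against 4.34, 4181 genes passed.

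**Figure D2:**
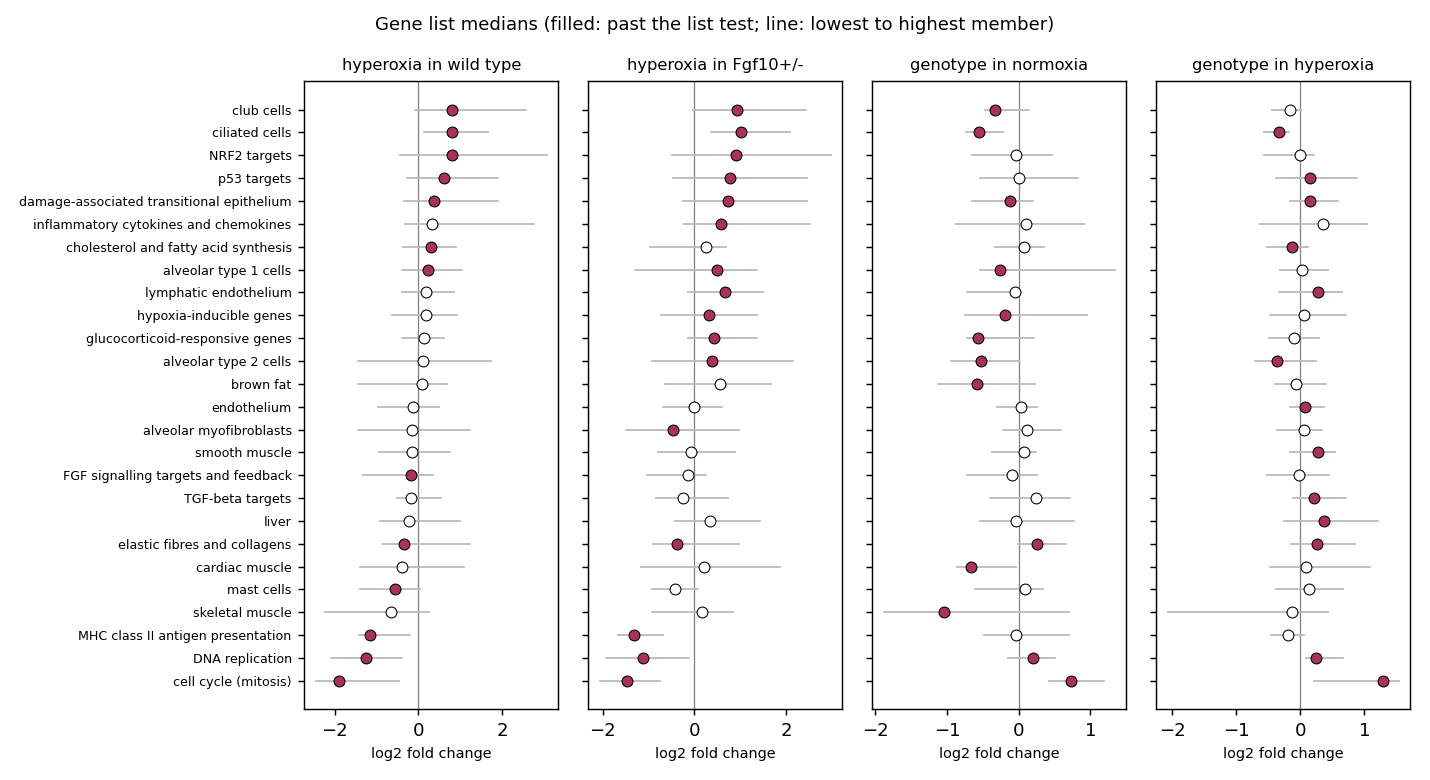
Median log2 fold change of each gene list (circles; filled where the camera list test passed adjusted p 0.05) in the comparisons, with a line from the lowest to the highest member. The mitosis list stands at -1.91 in wild-type hyperoxia, at -1.47 in hyperoxia of pups labelled Fgf10+/-, at 0.73 for genotype in normoxia and at 1.30 for genotype in hyperoxia.

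The responses of both genotypes to oxygen were then set side by side, using 2 comparisons with no array in common. Of the genes that passed in both, 1540 rose in both and 1331 fell in both, 2871 in all, where independent lists would share 272 and 189. Both comparisons take the spread of a gene from the same fit, so these expected numbers are a rough guide. Gpx2, Cdkn1a, Nmrk2, Inmt and Cxcl17 rose in both genotypes, and H1f5, Spc24 and Ccnb2 fell in both. Only 4 genes passed with opposite signs, and they are named here after their values were seen. Spink7, a protease inhibitor gene, moved by 0.43 (SE 0.14) in wild type and by -0.63 (SE 0.14) in pups labelled Fgf10+/-, the tendon transcription factor gene Scx by -0.34 (SE 0.10) and 0.34 (SE 0.10), the triglyceride lipase gene Pnpla2 by -0.31 (SE 0.10) and 0.35 (SE 0.10), and Gm648 by -0.66 (SE 0.20) and 0.76 (SE 0.20). Spink7 (group means 3.36 to 4.11) and Gm648 (3.32 to 4.39) lie under the array median of 4.50 in all 4 groups, near background, so their opposite signs are uncertain. The test of the difference between the genotypes passed for none of the 4 genes (interaction adjusted p between 0.466 and 0.499). Across all genes, which are not independent replicates, the fold changes correlated with r = 0.639. Of the 5762 genes called in either genotype, 95.6% changed in the same direction. Without replicate 4 of the wild-type normoxia arrays, 2430 genes passed in both with the same sign.

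**Figure D3:**
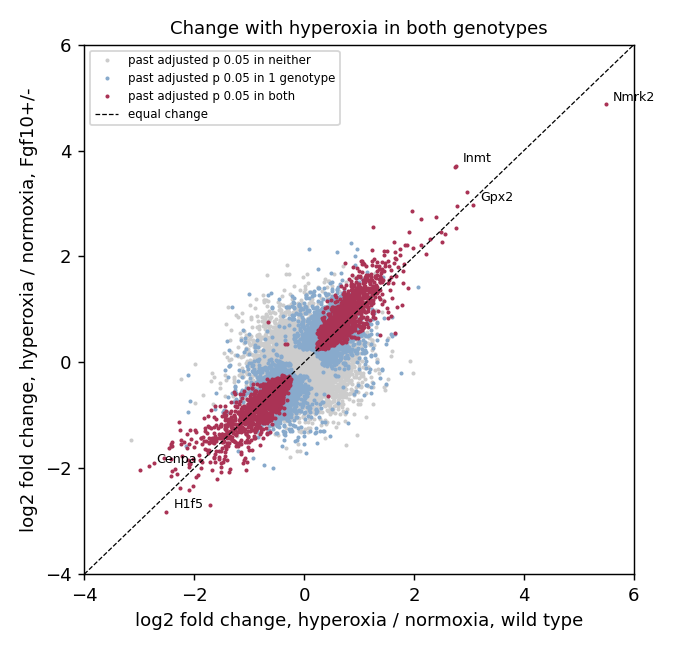
Log2 fold change of hyperoxia over normoxia for each of 20166 genes in wild-type pups (horizontal axis) and in pups labelled Fgf10+/- (vertical axis). Colours mark genes that passed adjusted p 0.05 in neither genotype, in a single genotype or in both, and the dashed line marks equal change. The 2871 genes that passed in both with the same sign spread along the line, with Nmrk2 farthest out at 5.48 and 4.87.

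Whether the response itself differed by genotype was tested with the interaction term. Limma called 0 of 20166 genes, with a smallest adjusted p of 0.466, while 1334 genes had an unadjusted p under 0.05 and 1008 would by chance. The 5 genes with the smallest p, none of which passed, were Macrod1 (0.74, SE 0.12), the peptide hormone gene Enho (0.78, SE 0.14), the transferrin receptor gene Tfr2 (1.62, SE 0.30), Rfesd (-1.67, SE 0.32) and Spink7 (-1.06, SE 0.20, under the array median in all groups), all at adjusted p = 0.466. Without replicate 2 of the wild-type hyperoxia arrays 1 gene passed, Tfr2 (1.85, SE 0.23, adjusted p = 0.0479). The mean of Tfr2 in the remaining wild-type hyperoxia arrays (4.25) lies under the array median of 4.50, so the size of this difference is uncertain. Abca3 stood at 0.21 (SE 0.14, adjusted p = 0.838) and Ager at 0.69 (SE 0.16, adjusted p = 0.501). Of 41 lists, camera called 9, with 8 more positive and 1 more negative in pups labelled Fgf10+/-, none of their members passed over all genes, and with an estimated correlation 0 lists were called. Among them were cardiac muscle (median 0.76, 1 higher adjusted over the list alone, camera adjusted p = 0.000123, and adjusted p = 0.264 with an estimated correlation) and transitional epithelium (median 0.37, 3 higher adjusted over the list alone, adjusted p = 0.000275, and adjusted p = 0.264 with an estimated correlation). The type 2 list had a median of 0.23 (0 adjusted over the list alone, adjusted p = 0.00293, and adjusted p = 0.377 with an estimated correlation). The mitosis list had a median of 0.49 (0 adjusted over the list alone, adjusted p = 0.00168, and adjusted p = 0.646 with an estimated correlation). Fry, a rotation test of direction, called 1 list, the p53 targets (median 0.17, fry adjusted p = 0.0419, camera adjusted p = 0.0557).

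The genotype comparison in normoxia asked what the lungs labelled Fgf10+/- look like without oxygen exposure. The directions that follow are those of the labels, since Fgf10 was not measurably lower. Of 20 genes of alveolar type 2 cells 8 were lower, among them the transporter Abca3 (1.65-fold lower, log2 -0.72, SE 0.10), the aspartic protease Napsa (-0.94, SE 0.12), Lpcat1 (-0.85, SE 0.12) and Etv5, a transcription factor downstream of FGF receptors (-0.73, SE 0.08). The type 1 marker Ager was lower by the same test (-0.54, SE 0.11, adjusted p = 0.0397, lost in 7 of 8 fits that left out 1 array). Of 18 genes of mitosis only Cdk1 was higher over all genes (0.84, SE 0.16, lost in 6 of 8), and the list, called by camera, had adjusted p = 0.2 with an estimated correlation. At limma adjusted p under 0.05, 23 genes were higher and 122 lower in the arrays labelled Fgf10+/-, 145 of 20166. Leaving out wild-type replicate 1, 2, 3 or 4 gave 44, 68, 65 or 292 genes, and leaving out replicate 2 or 4 labelled Fgf10+/- gave 68 or 59. A limma fit to these 8 arrays alone called 0 genes, and a fit with a heat-shock score as covariate, chosen after the arrays were seen, called 26.

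The largest rises in normoxia were in the chromosome cohesion gene Sgo2a (2.98-fold, log2 1.58, SE 0.24), Xkr5 (log2 1.42, SE 0.23), the cannabinoid receptor Cnr1 (2.25-fold, log2 1.17, SE 0.23) and Prr11 (2.17-fold, log2 1.12, SE 0.24). Plppr5 (1.08), the kinetochore gene Knl1 (0.98), the kinesin Kif23 (0.95), the prostaglandin receptor Ptger3 (0.93), Cd109 (0.88) and Cdk1 completed them. Large falls were in the slow myosin gene Myh7 (2.7-fold lower, log2 -1.43, SE 0.15), the secretoglobin Scgb1c1 (2.69-fold lower, log2 -1.43, SE 0.16) and the kisspeptin gene Kiss1 (2.46-fold lower, log2 -1.30, SE 0.23). They were followed by C2cd4b (-1.29), Daw1 (-1.28), the lipid droplet gene Cidec (-1.26), the proton pump subunit Atp6v1c2 (-1.18), the cardiac transcription factor Tbx20 (-1.17) and Myh7b (-1.15). Olfr1385, an olfactory receptor gene, stood at -1.52 (SE 0.32) between means of 4.08 and 2.56, both under the array median of 4.50, so its difference is read within the background. The lower group mean of Daw1, Xkr5 (3.43), Myh7b (3.83) and Tbx20 (4.43) also lies under that median, and the size of these differences is uncertain. Adjusted p-values ran from 0.000849, for Myh7, to 0.049, for Prr11 and Cd109. Sgo2a, Xkr5, Ptger3, Myh7, Scgb1c1, Atp6v1c2, Etv5, Napsa, Abca3 and Lpcat1 passed in all 8 fits that left out 1 array, while Cidec, Olfr1385 and Prr11 each lost their call in 7 of 8, Cd109 and Tbx20 in 6, C2cd4b, Cnr1, Kif23, Myh7b and Plppr5 in 5, Knl1 in 4, Kiss1 in 2 and Daw1 in 1.

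By list, 8 of 20 alveolar type 2 genes were lower in normoxia and 12 did not pass (15 lower adjusted over the list alone, median -0.53, camera adjusted p = 9.07e-18), the only list of this comparison to hold with an estimated correlation (adjusted p = 0.0178). Other epithelial lists were lower too. None of 16 ciliated cell genes passed over all genes (8 lower adjusted over the list alone, median -0.55, adjusted p = 9.26e-10, and adjusted p = 0.216 with an estimated correlation). None of 10 club cell genes did (3 lower adjusted over the list alone, median -0.33, adjusted p = 0.00176, and adjusted p = 0.373 with an estimated correlation). Of 14 type 1 genes, Ager was lower and 13 did not pass (2 lower and 1 higher adjusted over the list alone, median -0.26, adjusted p = 0.000638, and adjusted p = 0.2 with an estimated correlation). Of 13 transitional epithelium genes, Krt18 was lower (-0.65, SE 0.12, lost in 6 of 8 fits that left out 1 array) and 12 did not pass (3 lower adjusted over the list alone, median -0.12, adjusted p = 0.0442, and adjusted p = 0.532 with an estimated correlation). The transitional list lost its call without wild-type replicate 1 (adjusted p = 0.17) or 3 (0.0651) and without Fgf10+/- replicate 2 (0.0994), 3 (0.0736) or 4 (0.159). Of 18 mitosis genes, 1 was higher and 17 did not pass (18 higher adjusted over the list alone, median 0.73, adjusted p = 8.13e-16, and adjusted p = 0.2 with an estimated correlation). None of 15 DNA replication genes passed (0 adjusted over the list alone, median 0.20, adjusted p = 0.0107, and adjusted p = 0.62 with an estimated correlation), nor any of 18 genes of elastic fibres and collagens (0 adjusted over the list alone, median 0.25, adjusted p = 7.36e-06, and adjusted p = 0.285 with an estimated correlation). DNA replication lost its call without wild-type replicate 4 (0.0557) or Fgf10+/- replicate 1 (0.237). Of 12 glucocorticoid-responsive genes none passed (5 lower adjusted over the list alone, median -0.57, adjusted p = 0.000181, and adjusted p = 0.2 with an estimated correlation). Of 21 hypoxia-inducible genes, Bnip3 (-0.50, SE 0.09) and Pfkfb4 (-0.62, SE 0.12) were lower, each lost in 6 of 8 fits, and 19 did not pass (3 lower and 1 higher adjusted over the list alone, median -0.18, adjusted p = 0.0442, and adjusted p = 0.2 with an estimated correlation). This list lost its call without wild-type replicate 1 (0.0637) or 4 (0.11) or Fgf10+/- replicate 2 (0.175) or 4 (0.0673). The FGF targets list was not called (median -0.09, camera adjusted p = 0.113), with Etv5 lower and 13 of its 14 genes not passing.

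Gene lists of other tissues differed between these groups, while heat-shock genes differed between arrays of the same group. The list of immediate-early and heat-shock genes was not called by camera in any contrast. Of 15 cardiac muscle genes, Tnnt2 was lower in the normoxia arrays labelled Fgf10+/- (-0.81, SE 0.17, lost in 6 of 8 fits that left out 1 array) and 14 did not pass (9 lower adjusted over the list alone, median -0.67, camera adjusted p = 7.1e-07, and adjusted p = 0.2 with an estimated correlation). The skeletal muscle list (median -1.04, adjusted p = 0.00829, and adjusted p = 0.62 with an estimated correlation, no member passing, 0 adjusted over the list alone) and the brown fat list (median -0.58, adjusted p = 0.0442, and adjusted p = 0.533 with an estimated correlation, no member passing, 1 lower adjusted over the list alone) followed replicate 4 of the wild-type normoxia arrays. Without it their medians were -0.05 (adjusted p = 0.789) and -0.04 (adjusted p = 0.689). The brown fat list also lost its call without Fgf10+/- replicate 1 (0.0678), 2 (0.0994) or 4 (0.0647). The chaperone gene Hsph1 stood at 8.14, 8.15 and 8.17 in wild-type replicates 1 to 3 and at 8.63 in Fgf10+/- replicate 1, but at 10.17 in wild-type replicate 4 and at 10.29, 11.19 and 10.57 in Fgf10+/- replicates 2 to 4, so it parted the normoxia arrays across the genotypes. In the 8 hyperoxia arrays Hsph1 lay between 9.39 and 9.99, above wild-type normoxia replicates 1 to 3, and its change with oxygen did not pass (1.00, SE 0.50, adjusted p = 0.186 in wild type; -0.30, SE 0.50, adjusted p = 0.734 in pups labelled Fgf10+/-). The cold-induced gene Rbm3 fell with oxygen in both genotypes (-0.40, SE 0.12, adjusted p = 0.0274, and -0.41, SE 0.12, adjusted p = 0.0206). The other cold-induced gene, Cirbp, did not pass and had opposite signs (-0.19, SE 0.37, adjusted p = 0.789 in wild type and 0.29, SE 0.37, adjusted p = 0.645 in pups labelled Fgf10+/-). With the heat-shock score as covariate 4022 genes passed in wild-type hyperoxia and 4992 in hyperoxia of pups labelled Fgf10+/-. Hsph1, Rbm3 and Cirbp were chosen after their values were seen.

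**Figure D4:**
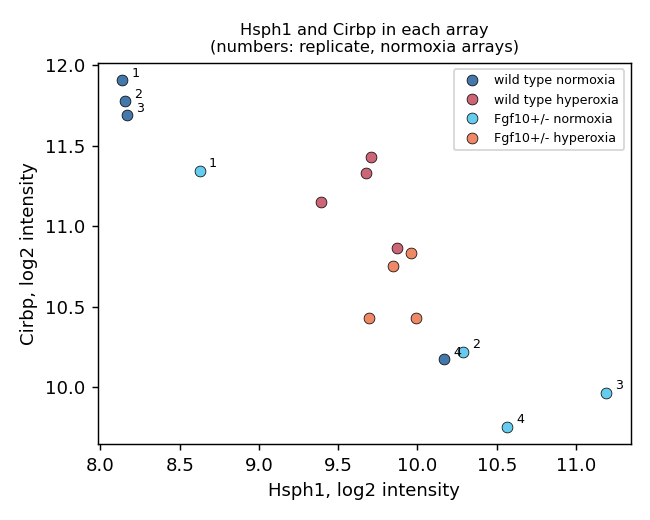
Log2 intensity of the heat-shock gene Hsph1 against that of the cold-induced gene Cirbp in each array. In 4 of the 8 normoxia arrays, 1 wild type and 3 labelled Fgf10+/-, Hsph1 lies between 10.17 and 11.19, and in the other 4 between 8.14 and 8.63; in the hyperoxia arrays it lies between 9.39 and 9.99. Both genes were chosen after their values were seen.

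**Figure D5:**
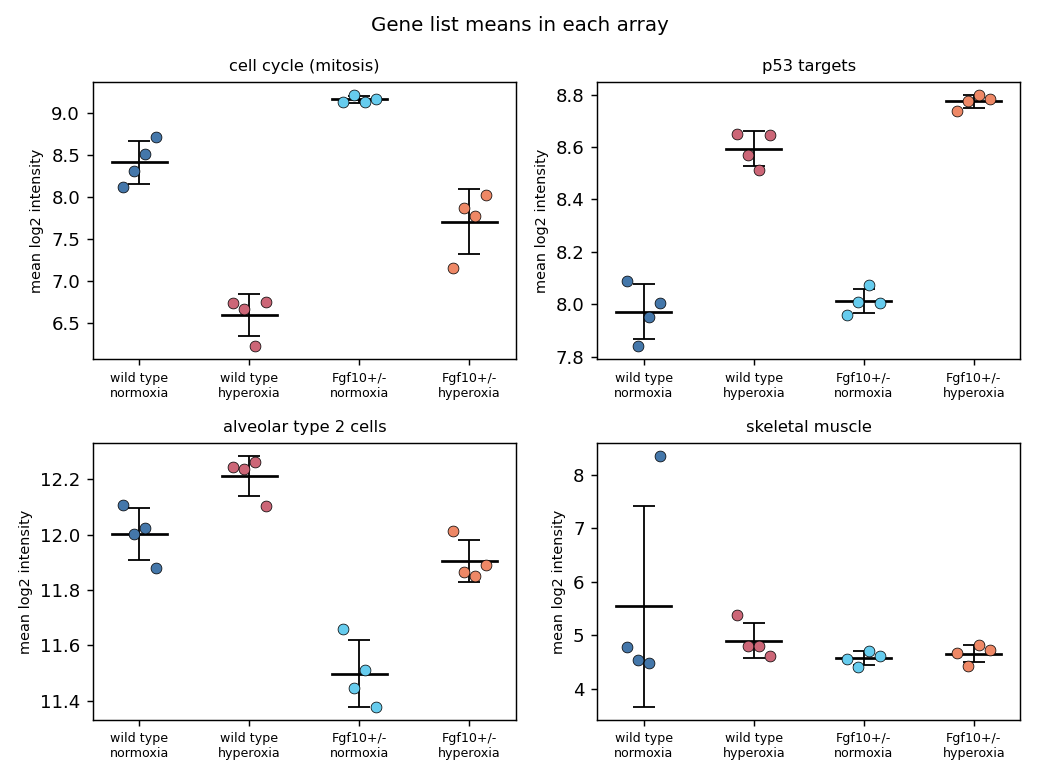
Mean log2 intensity of gene lists in each array (points), by genotype and oxygen level, with the group mean and SD. The skeletal muscle list stands at 8.36 in 1 wild-type normoxia array, apart from the other arrays of its group.

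The last comparison asked how the genotypes differed after oxygen exposure. The largest rises in the hyperoxia arrays labelled Fgf10+/- were in Ckap2, a microtubule-associated protein (3.34-fold, log2 1.74, SE 0.21), and Prc1, which bundles microtubules in cytokinesis (3.07-fold, log2 1.62, SE 0.22). Of 18 genes of mitosis 11 were higher (adjusted p = 0.0519 for the list with an estimated correlation). Of 20 genes of alveolar type 2 cells 4 were lower (adjusted p = 0.0519 for the list with an estimated correlation), including the phosphate transporter Slc34a2 (1.64-fold lower, log2 -0.71, SE 0.13) and Abca3 (1.43-fold lower, log2 -0.51, SE 0.10), calls lost in 7 of 8 fits that left out 1 array. Ager stood at 0.15 (SE 0.11, adjusted p = 0.757). At limma adjusted p under 0.05, 59 genes were higher and 24 lower, 83 of 20166, again by the labels and with Fgf10 itself at -0.21 (adjusted p = 0.835). The count of genes fell to 32, 46, 20 or 29 without wild-type replicate 1, 2, 3 or 4 and to 21, 30 or 13 without Fgf10+/- replicate 2, 3 or 4, and it was 80 without Fgf10+/- replicate 1. A limma fit to these 8 arrays alone called 0 genes, a fit with sex as covariate 52 and a fit with the replicate number as a block 37.

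The other large rises in hyperoxia were in Pimreg (2.94-fold, log2 1.56, SE 0.27), the centromere motor Cenpe (2.91-fold, log2 1.54, SE 0.29), the kinesins Kif20a (1.48), Kif18b (1.46) and Kif22 (1.43), the spindle gene Aspm (1.46), Top2a (1.45) and Ccnb2 (1.43, SE 0.18). The largest falls were in Kiss1 (3.46-fold lower, log2 -1.79, SE 0.23), Bex2 (1.88-fold lower, log2 -0.91, SE 0.15) and the adenylate kinase Ak4 (1.81-fold lower, log2 -0.86, SE 0.14). They were followed by the epithelial transcription factor Tfcp2l1 (-0.81), the alanine transaminase Gpt (-0.79), Spink7 (-0.75), Myh7 (-0.74), Fam178b (-0.72), Slc34a2 (-0.71) and Lgi3 (-0.67). Spink7 (4.11 and 3.36) lies under the array median of 4.50 in both groups and Kif18b (4.00) in wild type, so the size of these differences is uncertain. Adjusted p-values ran from 0.00904, for Ckap2, Ccnb2 and Kiss1, to 0.0479, for Myh7. Ckap2, Prc1, Ccnb2, Kiss1 and Lgi3 passed in all 8 fits that left out 1 array, while Gpt, Fam178b and Myh7 lost their calls in 8 of 8, Spink7 and Tfcp2l1 in 7, Aspm, Cenpe and Pimreg in 6, Ak4, Kif22 and Top2a in 5, Bex2 and Kif18b in 4 and Kif20a in 3.

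By list, 11 of 18 mitosis genes were higher in hyperoxia arrays labelled Fgf10+/- and 7 did not pass (16 adjusted over the list alone, median 1.30, camera adjusted p = 1.01e-31, and adjusted p = 0.0519 with an estimated correlation). Birc5 stood at 1.39 (SE 0.22) and Cdc20 at 1.29 (SE 0.21), calls lost in 3 and 5 of 8 fits that left out 1 array. Of 20 type 2 genes, 4 were lower and 16 did not pass (8 lower adjusted over the list alone, median -0.36, adjusted p = 6.17e-11, and adjusted p = 0.0519 with an estimated correlation), namely Slc34a2, Lamp3 (-0.53, SE 0.10), Abca3 and Etv5 (-0.41, SE 0.08). Lamp3 lost its call in 6 and Etv5 in 8 of these fits. None of 20 p53 targets passed over all genes (5 higher and 1 lower adjusted over the list alone, median 0.15, adjusted p = 0.00534, and adjusted p = 0.0519 with an estimated correlation). Of 18 genes of elastic fibres and collagens, the crosslinking enzyme Loxl2 was higher (0.85, SE 0.14, lost in 5 of 8) and 17 did not pass (1 adjusted over the list alone, median 0.26, adjusted p = 1.54e-07, and adjusted p = 0.213 with an estimated correlation). None of 10 smooth muscle genes passed (4 higher adjusted over the list alone, median 0.28, adjusted p = 0.000101, and adjusted p = 0.21 with an estimated correlation), none of 16 ciliated cell genes (0 adjusted over the list alone, median -0.33, adjusted p = 1.97e-05, and adjusted p = 0.505 with an estimated correlation) and none of 15 DNA replication genes (0 adjusted over the list alone, median 0.25, adjusted p = 9.31e-05, and adjusted p = 0.519 with an estimated correlation). Of 6 lymphatic endothelial genes Mmrn1 was higher (0.66, SE 0.13, lost in 8 of 8) and 5 did not pass (1 adjusted over the list alone, median 0.28, adjusted p = 0.0127, and adjusted p = 0.365 with an estimated correlation). The cholesterol and fatty acid synthesis list was lower with no member passing (0 adjusted over the list alone, median -0.13, adjusted p = 0.00202, and adjusted p = 0.213 with an estimated correlation).

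Some list calls between the genotypes in hyperoxia rested on single arrays. The liver list (median 0.37, camera adjusted p = 0.015, and adjusted p = 0.213 with an estimated correlation, no member passing, 0 adjusted over the list alone) was lost without Fgf10+/- replicate 2 (median 0.23, adjusted p = 0.409). The TGF-beta targets (median 0.21, adjusted p = 0.0134, and adjusted p = 0.213 with an estimated correlation, no member passing, 0 adjusted over the list alone) were lost without wild-type replicate 2 (adjusted p = 0.0561). The endothelium list (median 0.07, adjusted p = 0.0414, and adjusted p = 0.626 with an estimated correlation, no member passing, 0 adjusted over the list alone) was lost without wild-type replicate 1 (0.148) or 2 (0.186) and without Fgf10+/- replicate 2 (0.0533) or 3 (0.318). The transitional epithelium list (median 0.16, adjusted p = 0.0337, and adjusted p = 0.519 with an estimated correlation, no member passing, 1 higher adjusted over the list alone) was lost without wild-type replicate 1 (0.0551) or 4 (0.111) and without Fgf10+/- replicate 1 (0.186) or 4 (0.0724).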

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

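The search for single arrays apart from their group and the tests of genotype differences were fixed before the data were examined, whereas the test of features that name no gene was not in that plan and counts as chosen after the data were seen.

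Among 460 groups of 4 arrays examined for named genes and gene lists, 23 held 1 array whose gap to its nearest neighbour took up more than 0.829 of the range of the group. Chance alone gives such a gap in about 1 in 20 groups, which is what was seen. The groups share arrays and some genes, so this match does not tell whether a given array stands apart by chance. The values below are the difference (log2) of that array from the mean of the other 3. For gene lists an array stood apart in 8 of these groups of arrays, with the liver list in a pair of them. Skeletal muscle genes were 3.76 higher in wild-type normoxia replicate 4 (8.36 against 4.60). Liver genes were 1.15 higher in Fgf10+/- hyperoxia replicate 2 (5.49 against 4.34) and 0.27 higher in Fgf10+/- normoxia replicate 4. Inflammatory genes were 1.44 higher in Fgf10+/- hyperoxia replicate 1 (7.06 against 5.62), where pericyte genes stood at -0.23. The mitosis list stood at -0.50 in wild-type hyperoxia replicate 3, lymphatic endothelium at -0.16 in wild-type hyperoxia replicate 1, and alveolar type 2 genes at -0.15 in wild-type hyperoxia replicate 4.

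For 15 values of named genes an array stood apart in the same way. Wild-type hyperoxia replicate 3 held Iqgap3 at -2.28, H2ac4 at -1.29 and Top2a at -1.30 from the other 3 arrays, along with the low mitosis list, and C2cd4b at 0.49. Wild-type hyperoxia replicate 4 held Gpx2 at -0.36 and Tfcp2l1 at -0.33, and replicate 2 held Tfr2 at 0.91. Fgf10+/- hyperoxia replicate 1 held H2ac4 at -1.23, Aldh3a1 at 0.44 and Myh7b at 0.30. In normoxia, Fgf10+/- replicate 4 held Cidec at 0.88 and replicate 2 held Prc1 at -0.080. Wild-type replicate 3 held Prr11 at -0.63, and replicate 2 held Daw1 at -0.78 and Ak4 at 0.32. No explanation of these arrays was tested.

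For 9 gene lists the response to hyperoxia differed between the genotypes by the camera test of the interaction. The median interaction, positive where the change was higher in pups labelled Fgf10+/-, was 0.76 for cardiac muscle, 0.50 for lymphatic endothelium, 0.49 for mitosis, 0.37 for transitional epithelium, 0.33 for glucocorticoid-responsive genes, 0.23 for alveolar type 2 cells, 0.19 for type 1 cells, 0.13 for hypoxia-inducible genes and -0.23 for cholesterol and fatty acid synthesis. With an estimated correlation between genes 0 of these 9 lists were called. Cardiac muscle, a list of another tissue, was not called by camera in wild-type hyperoxia (median -0.39, adjusted p = 0.152). Nor was it called in hyperoxia of pups labelled Fgf10+/- (median 0.20, adjusted p = 0.32), and it already differed between the genotypes in normoxia. The lymphatic list lost its call without Fgf10+/- normoxia replicate 3 (adjusted p = 0.0725), and the hypoxia-inducible genes without Fgf10+/- normoxia replicate 2 (0.0774) or hyperoxia replicate 1 (0.0549). The glucocorticoid-responsive genes lost it without wild-type normoxia replicate 1 (0.0542), wild-type hyperoxia replicate 2 (0.0895), Fgf10+/- normoxia replicate 2 (0.0743) or Fgf10+/- hyperoxia replicate 1 (0.0549). For single genes limma called 0 (1334 at an unadjusted p under 0.05). Since the real count is 0, all 100 of 100 draws of genotype assignments had to give at least as many (highest 32), so the draws say nothing about the interaction.

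Of 31490 features that name no gene and have no missing value, 327 passed the threshold in wild-type hyperoxia (101 higher and 226 lower, 1.04%) and 611 in hyperoxia of pups labelled Fgf10+/- (207 higher and 404 lower, 1.94%). In the genotype comparisons 1 feature passed in normoxia and 0 in hyperoxia by limma. What these features measure is not given in the sources used here.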

How the results depend on the processing

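The alternatives with a heat-shock covariate were chosen after the arrays were seen, and the others before the data were examined.

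Both hyperoxia counts stayed within 1.5 times their value under every alternative except the fold minimum, which by its construction left 2140 genes in wild type, 2845 in pups labelled Fgf10+/- and 1517 shared with the same sign. Leaving out 1 array gave 3079 to 3498, 3998 to 4602 and 2397 to 2865 genes. No test result that passed in the main fit or in an alternative had the opposite sign in the other. Results that passed in neither could change sign. Fgf10 in wild-type hyperoxia stood at 0.06 for the feature tested and at -0.09 for the mean of its features.

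The genotype counts moved, and unless stated the cause was not tested. In normoxia the 145 genes became 283 under the stricter filter, 94 with the mean of all features, 433 with trend and robust options, 306 with array weights, 0 in a fit to the 2 groups alone and 26 with the heat-shock covariate. In hyperoxia the 83 became 126 under the stricter filter, 223 with trend and robust options, 0 in a fit to the 2 groups alone, 37 with the replicate block and 52 with the sex covariate. Leaving out 1 array gave 44 to 292 in normoxia and 13 to 80 in hyperoxia. The interaction called 0 genes in every fit run but 1 (leaving out 1 array, 0 to 1), where Tfr2 passed without wild-type hyperoxia replicate 2.

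The lower Fgf10 signal in hyperoxia of pups labelled Fgf10+/- was -0.64 in the fit to 2 groups, no longer past the threshold (adjusted p = 0.0586), and ran from -0.77 to -0.51 when 1 array was left out. With an estimated correlation, 1 list was called in each hyperoxia comparison, 1 for genotype in normoxia, 0 for genotype in hyperoxia and 0 for the interaction. The cause was not tested. For genotype in hyperoxia 8 lists were called on ranks and 4 by fry, and fry called 1 for the interaction. Leaving out 1 array gave 7 to 14 lists for the interaction, the highest without wild-type normoxia replicate 2. Of 64 list calls, fry lost 25, ranks 11, the stricter filter 10, the sex and the heat-shock covariates 7 each, the mean of features 3, the block 2 and quantile normalization 1. Of 203 calls of named genes, the fit to 2 groups lost 60, the heat-shock covariate 35, the sex covariate and the block 26 each, the mean of features 21, quantile normalization 7, no filter 6 and scaling 2. Scaling shifted arrays by -0.03 to 0.02 (log2).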

Other observations

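The tests of features outside the deleted part, of all genotype labels exchanged, of a lower share of all epithelium and of labels exchanged between 1 array of each genotype were chosen after the result was seen, as were the heat-shock covariate, the split of the normoxia arrays as a pattern, and the genes named here.

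Other splits of the 8 arrays of each comparison, run in the same fit of all 16 arrays, show how many genes other groupings give. In wild-type hyperoxia only 1 of 35 splits, the real one, gave as many as 3846 genes (highest other 0). In hyperoxia of pups labelled Fgf10+/- 1 of 35 gave as many as 4791 (highest other 7). For genotype in hyperoxia 1 of 35 gave as many as 83 (highest other 13). This is the smallest share that 35 splits allow, so chance is argued against for these counts but not excluded. Fits to the 8 arrays of either genotype comparison alone called no genes. For genotype in normoxia 2 of 35 splits gave as many as 145, the other with 372 genes. The splits therefore do not argue against chance for that count, and the arrays have a structure other than genotype. The 19 genes given below passed in hyperoxia arrays as well. Both comparisons take the spread of a gene from the same fit, so the number that independent lists would share is only a rough guide. All 19 had the same sign in separate arrays, which a shared spread does not produce, so chance is argued against for those genes.

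That structure set wild-type replicate 4 and Fgf10+/- replicates 2 to 4 apart from the other 4 normoxia arrays, with 193 genes higher and 179 lower, 6 of them also called for genotype. Hsph1 was 2.28 higher, the chaperone genes Chordc1, Dnaja1 and Hspa5 1.06, 1.00 and 1.00 higher, and the cold-induced genes Cirbp and Rbm3 differed by -1.65 and by only -0.25, and the immediate-early gene Nr4a1 by -1.53. On 13 further heat-shock genes, not among the first 60 of the split, it ranked 1 of 35 splits (difference 0.54). The split was recognized by heat-shock genes in these same arrays, and further heat-shock genes can follow them whatever the trigger. The rank therefore does not single out a trigger. Body temperature at collection is a candidate explanation, with handling or time of collection left open. Labels exchanged between wild-type replicate 4 and Fgf10+/- replicate 1 are argued against by the 83 genes called for genotype in hyperoxia, on which Fgf10+/- replicate 1 scored 0.27, with its group (0.31, 0.23 and 0.26), and wild-type replicate 4 scored -0.15.

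The Fgf10 signal was not measurably lower in the arrays labelled Fgf10+/-: 10 of 10 features were higher in normoxia and 0 of 10 in hyperoxia (mean difference -0.21, exact permutation p = 0.229). Labels without any relation to genotype are argued against by the chromosome around the gene: the 40 genes nearest to Fgf10 differed between the genotypes, averaged over both oxygen levels, with a mean absolute t of 1.79 against a median of 1.16 for windows of 40 neighbours, percentile 99.76 of 20134 windows. By the number of neighbours with an unadjusted p under 0.05, which was 8, the percentile was only 77.5, so a few genes carry the difference. Labels exchanged between all arrays stay open (difference in Fgf10 averaged over both oxygen levels 0.13), and so do features outside the deleted part, since the lowest difference of any feature in normoxia was 0.072 and a transcript of the changed allele may still be detected. The 5 neighbours past the adjusted threshold, which may differ through chromosome segments linked to the targeted allele, were Nnt (0.53, SE 0.08), Paip1 (0.70, SE 0.11), 4833420G17Rik (-0.73, SE 0.06), Emb (-0.57, SE 0.10) and AF067061 (-0.76, SE 0.10).

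Alveolar type 2 genes were lower in the normoxia arrays labelled Fgf10+/-, with a list median of -0.53. Sex of the pups is argued against as the whole cause, since the median with a sex covariate was -0.53, and so is the heat-shock difference between the arrays, since the median with that covariate was -0.41 and the list kept its call in both fits. A lower share of all epithelium remains a candidate explanation: the type 1, club and ciliated genes had a median of -0.40, and the type 2 genes differed from them by -0.12 (bootstrap 95% interval -0.39 to 0.05). The bootstrap drew genes, which are not independent, and not arrays, so its interval leaves out the spread between pups. Whether genotype acts on type 2 cells or on the amount of epithelium cannot be decided from whole-lung homogenate, and the genotype itself was not checked by Fgf10.

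The genotype comparisons in normoxia and hyperoxia share no array, and 19 genes passed in both, all with the same sign, where independent lists would share 0.0673 higher and 0.145 lower. They do share the spread of each gene, so genes with a small spread can pass in both more often than that. The 3 higher were Igf1 (0.79 in normoxia and 0.78 in hyperoxia), Gas2l3 (0.74 and 0.80) and Cenpp (0.57 and 0.68). Among the 16 lower were Kiss1 (-1.30 and -1.79), Myh7 (-1.43 and -0.74), Slc34a2 (-0.80 and -0.71), Tfcp2l1 (-0.73 and -0.81), Elf5 (-0.91 and -0.66), Abca3 (-0.72 and -0.51), Etv5 (-0.73 and -0.41) and Lgi3 (-0.64 and -0.67). The 16 also held 4833420G17Rik (-0.77 and -0.70), a neighbour of Fgf10 that may differ through a chromosome segment linked to the targeted allele. Across all genes, which are not independent, the fold changes correlated with r = 0.155.

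Of 16 circadian clock genes, 4 fell, 2 rose and 10 did not pass in wild-type hyperoxia (5 fell and 2 rose adjusted over the list alone). Among those that fell were Dbp, which fell by 2.10 (SE 0.34), Nr1d2, which fell by 1.33 (SE 0.19), and Tef, which fell by 1.16 (SE 0.15). In pups labelled Fgf10+/-, 2 of the 16 fell and 14 did not pass (5 fell and 2 rose adjusted over the list alone). Nr1d2 fell by 1.04 and Tef fell by 0.60, and Dbp stood at -0.93 (adjusted p = 0.0628). Camera did not call the interaction of this list. The list of 16 clock genes was not called by camera in wild-type hyperoxia (adjusted p = 0.171) and was called by fry (0.00111), and in pups labelled Fgf10+/- neither camera (0.501) nor fry (0.13) called it. For genotype in normoxia its median was -0.21, with 1 gene lower and 15 not passing (3 lower adjusted over the list alone), not called by camera (adjusted p = 0.0664) and called by fry (0.0131).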
